A study of Mus musculus with 8 samples.

How the data were processed

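The tissue was subplate microdissected from the somatosensory cortex of newborn mice (postnatal day 0), and each of the 8 libraries was made from a pool of 2 brains per the labels. Separate pools are taken as separate samples as far as the labels state. The groups are controls and mutants of an Emx1Cre line and of a NexCre line crossed to a conditional Lhx2 allele, with 2 libraries in each of 4 groups. Libraries were sequenced as paired reads of 100 bp per the labels. The deposited values are counts of reads per gene, made by the authors before deposition, in 1 table per line. Per the submitters' processing notes the tools were HISAT2, SAMtools and DESeq2 with genome build mm10. Their versions, the program that counted reads, its annotation and the strand setting are not given in the sources used here.

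The 2 tables were joined by gene symbol into 55202 genes, and 53437 of them (96.8%) were matched to GENCODE M21 for biotype and position. Symbols that a spreadsheet had turned into date numbers were left out, because the number no longer names a gene: 26 in the Emx1Cre table and 24 in the NexCre table, which held 0.239% to 0.269% of the reads. All per-sample columns were used. The 37 mitochondrial genes held 0 reads in every library. Total reads ran from 31.2 to 64.4 M per library, and 17592 to 21760 genes had at least 10 reads. The biological coefficient of variation was 26.2%. Replicates differed by a chi-square per degree of freedom of 74.4, 87.7, 25.9 and 27.5 in Emx1Cre controls, Emx1Cre mutants, NexCre controls and NexCre mutants, where counting error alone gives 1. With 2 libraries against 2, the smallest exact two-sided permutation p is 0.333, so every p for a gene rests on a spread shared across genes and groups.

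The groups, comparisons, tests, gene lists and rule for named genes were written before the data were examined. Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 22820. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit, prior count 0.125) in R 4.3.3, with all 8 libraries in 1 fit, group as the only term, 4 residual degrees of freedom and 5.95 prior degrees of freedom. The quasi-likelihood F test was two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Comparisons were mutants against controls in each line, the difference of these 2 effects, and NexCre controls against Emx1Cre controls. Genes called in both lines were counted against the overlap expected of independent lists, with Fisher's exact test. Standard errors come from the fit, and log values per library use a pseudocount of 0.5 CPM.

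Gene lists were tested with camera of limma 3.58.1 on the same fit, with a preset correlation of 0.01 between genes and adjustment over 31 lists. The 33 lists were: subplate neurons, deep layers, upper layers, area patterning, guidance, adhesion, extracellular matrix, ion channels, glutamate and GABA receptors, synaptic vesicles, immediate early genes, radial glia, intermediate progenitors, cell cycle, interneurons, oligodendrocytes, astrocytes, microglia, endothelium, meninges, choroid plexus, erythroid cells, Cajal-Retzius cells, striatum, thalamus, hippocampus, piriform cortex and amygdala, mitochondrial transcripts, ribosomal proteins, stress, apoptosis, neurotrophic factors and sex-linked transcripts. A list needed 3 tested members. The mitochondrial list had 0, and the sex-linked list served to describe the pools and entered no set test. Lists are given with their camera test, those that passed it in a mutant comparison also with their members called over all genes, and most of those with members called when adjusted over the list alone are given with that count.

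Lhx2, Emx1 and Neurod6 were always named. In each mutant comparison the rule named the 10 largest changes in each direction among genes called, with a mean of at least 1 CPM over the line's 4 libraries, both mutants on the same side of both controls and no placeholder name or pseudogene. It named 5 each way for the difference of effects and for the controls, up to 10 for both lines, and per list up to 4 called members or, with none called, the 2 with the lowest p as values. Agt, Aldh1l1, Apoe, Aqp4, Slc1a2, Gria1, Gabrb1, Mef2c, Nr4a2, Nxph4, Plxnc1, Tac1, Tcf7l2, Ttr, Rn7sk, Plcxd2, Gucy1a1, Hist1h2al, Ccl19-ps3, Gm2564 and Gm3279 fall outside it and were chosen after their values were seen. Not every result that the rule names for lists is reported here.

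Alternatives written before the data were examined were median-of-ratios (RLE) and upper-quartile scaling, no low-count filter, a strict filter (1 CPM in 2 libraries and a mean of 20 counts), DESeq2 1.42.0 with its own size factors, each line fitted alone, a replicate block, removal of mitochondrial, haemoglobin and sex-linked genes, leaving out each library in turn, a threshold of 0.10 for genes in both lines, and an estimated correlation for lists. Chosen after seeing the data were protein-coding genes only, a covariate from Y-linked genes, and a replicate block in the Emx1Cre line only. The pipeline was tested on simulated data with 200 genes changed in the Emx1Cre line and 0 in the NexCre line, over 3 simulations. On average edgeR called 134.3 genes, 11.3 of them false, and recovered 39.0% of genes changed 2-fold and 84.0% of those changed 4-fold, and it called 1.33 genes in the line with no change. DESeq2 called 190.7, 39.0 of them false, and 10.7 in the line with no change. A list of 20 shifted genes had p = 9.02e-36 with the preset and 0.000167 with an estimated correlation in camera of limma, against 0.132 and 0.322 for an unshifted list. Simulated genes were drawn independently, whereas the estimated correlation in Emx1Cre mutants was 0.297 for astrocyte markers and 0.716 for striatal markers. The simulation therefore does not test the preset of 0.01 for such lists.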

Results

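Gene expression was measured in subplate tissue microdissected from the somatosensory cortex of newborn mice (postnatal day 0). The subplate is the deepest layer of the developing cortex and the layer in which thalamic axons pause before they enter the cortical plate. The LIM-homeodomain gene Lhx2 had been deleted in 2 ways. Emx1Cre11.5 recombines in cortical progenitors, and NexCre, driven from the Neurod6 locus, recombines in postmitotic excitatory neurons. The 8 libraries form 4 groups of 2: Emx1Cre controls, Emx1Cre mutants, NexCre controls and NexCre mutants. Each library came from a pool of 2 brains, so n = 2 pools in every group below. The libraries held 64.4 and 40.8 M reads in Emx1Cre controls, 56.9 and 42.6 M in Emx1Cre mutants, 31.2 and 38.7 M in NexCre controls, and 36.8 and 38.9 M in NexCre mutants. Expression per library is given as CPM scaled by TMM, and each error is the standard error (SE) of the log2 fold change. Genes called changed passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

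The libraries of the Emx1Cre line and of the NexCre line stood apart in composition. The first principal component held 78.4% of the variance and separated the 2 lines. The small nuclear RNA Rn7sk made up 1.42 to 32.4 CPM, unscaled, in the Emx1Cre libraries and 18425 to 23101 in the NexCre libraries. Transcripts of histone genes, most of which lack a poly(A) tail, took 0.0325% to 0.0383% of reads in the Emx1Cre libraries and 0.764% to 0.925% in the NexCre libraries. Within the Emx1Cre line, small RNA took 0.0556% and 0.0585% of reads in control 1 and mutant 1 and 0.441% and 0.576% in control 2 and mutant 2. The mutant comparisons were made within each line, which keeps the difference between the lines out of the fold changes but not the differences between libraries of a line. The spread was estimated from both lines together, so the p-values and calls of each line also depend on the libraries of the other. Markers of neighbouring tissues were high in single libraries. The striatal genes Penk and Tac1 reached 55.1 and 47.0 CPM in Emx1Cre mutant 2, against at most 10.9 and 6.33 CPM in the other Emx1Cre libraries. The thalamic genes Tcf7l2, Lhx9 and Zic1 reached 42.9, 59.9 and 83.3 CPM in NexCre control 1, against at most 5.99, 1.85 and 18.6 CPM in the other NexCre libraries. Ttr, the choroid plexus transthyretin, reached 1966 CPM in NexCre mutant 1 and 346 CPM in NexCre control 1, against 4.39 and 20.2 CPM in the other 2 NexCre libraries.

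The targeted gene was examined first. Lhx2 (chromosome 2, 38339281 to 38369733, mm10) stood at 90.4 and 91.5 CPM in Emx1Cre controls and at 64.0 and 42.7 CPM in Emx1Cre mutants. The log2 fold change was −0.77 ± 0.20 (95% interval −1.21 to −0.32), with an adjusted p of 0.273 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called the same difference, with a log2 fold change of −0.77 ± 0.22 and an adjusted p of 0.0328. Without Emx1Cre mutant 2 the edgeR value was −0.50, and without Emx1Cre mutant 1 it was −1.10. In the NexCre line Lhx2 stood at 182 and 236 CPM in controls and at 227 and 245 CPM in the libraries labelled mutant. Its log2 fold change there was 0.18 ± 0.20 (95% interval −0.26 to 0.62), so the level of the whole gene was not lower in the libraries labelled NexCre mutant. Without NexCre control 1 it was 0.00074, and without NexCre control 2 it was 0.38. Counts are given per gene, so they do not separate deleted exons from the others and check the labels only in part. Emx1 (chromosome 6, 85187438 to 85204462), the homeobox gene whose locus drives Emx1Cre, fell in Emx1Cre mutants by 1.66 ± 0.22 on the log2 scale, from 66.4 and 78.4 to 24.6 and 20.99 CPM. In the NexCre line Emx1 had a log2 fold change of −0.61 ± 0.22, which was not called, and CPM of 32.1, 50.3, 27.8 and 26.3 in control 1, control 2, mutant 1 and mutant 2. Neurod6 (chromosome 6, 55677822 to 55681263), a transcription factor of cortical excitatory neurons and the NexCre locus, was called in neither line. Its log2 fold change was −0.28 ± 0.23 (95% interval −0.79 to 0.23) in Emx1Cre mutants, and the CPM of that line were 336, 309, 323 and 209. In NexCre mutants it was −0.75 ± 0.23 (95% interval −1.26 to −0.24), and the CPM were 395, 507, 308 and 228.

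**Figure D1:**
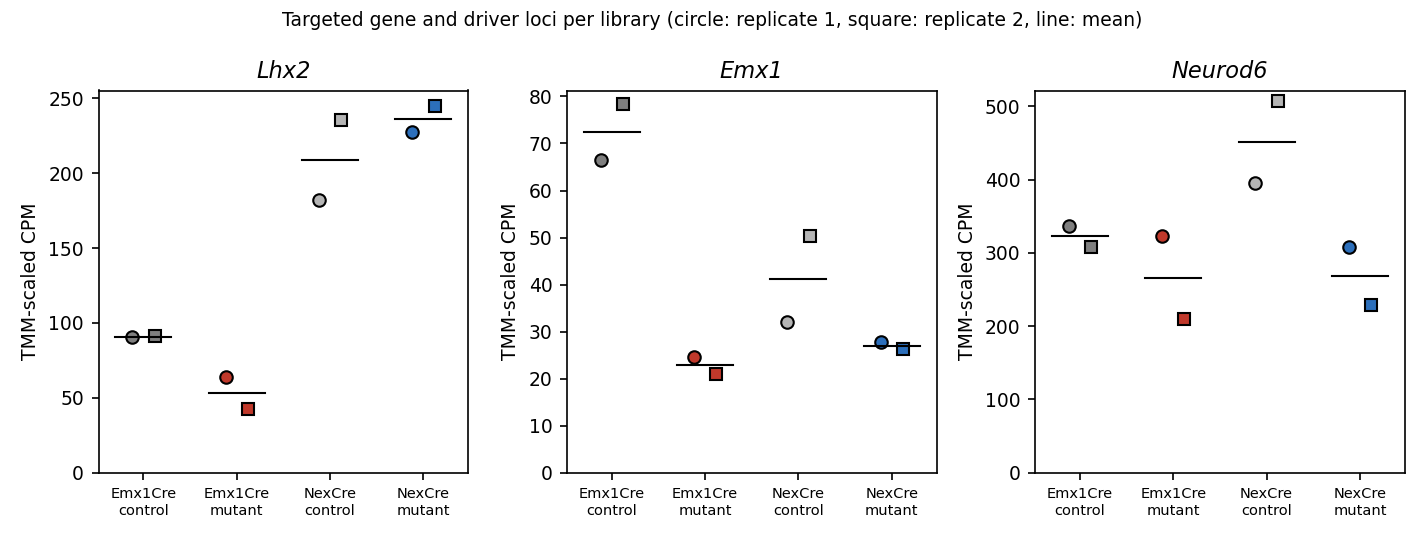
TMM-scaled CPM (vertical axes) of Lhx2, Emx1 and Neurod6 in each of the 8 libraries, by group (horizontal axes), with a point per pool and a line at each group's mean. Lhx2 lies at 64.0 and 42.7 CPM in Emx1Cre mutants against 90.4 and 91.5 CPM in their controls, and at 227 and 245 CPM in NexCre mutants against 182 and 236 CPM in their controls.

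The comparison of Emx1Cre mutants with their controls asks what changes in the subplate when Lhx2 is removed from cortical progenitors. The controls of both lines are labelled wild type. If they lack the Cre allele, its effect cannot be told apart from that of Lhx2 loss in either line. The transcription factors Pou3f1, Pou3f2 and Prdm8 fell in the mutants, by 2.24 ± 0.28, 1.52 ± 0.18 and 1.74 ± 0.22 on the log2 scale. Inhba, which encodes an activin subunit, fell by 2.34 ± 0.27 (chromosome 13, 16011851 to 16031621), from 13.7 and 16.8 to 3.81 and 2.15 CPM. Slc6a4, the serotonin transporter, which thalamic neurons that project to the cortex carry at this age, rose by 2.48 ± 0.32 (chromosome 11, 76998603 to 77032340), from 2.95 and 3.38 to 19.2 and 15.9 CPM. The homeobox gene Msx3 (chromosome 7, 140046157 to 140049089) fell to near absence, from 248 and 275 reads in controls to 4 and 0 reads in mutants.

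Of 22820 genes tested, 18 were called in Emx1Cre mutants, 5 higher and 13 lower, each at an adjusted p of 0.0334 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Besides Slc6a4, the genes that rose were Col23a1, a transmembrane collagen (1.65 ± 0.18), Etl4 (1.44 ± 0.20), Sparcl1, a synapse-promoting matrix protein secreted by astrocytes (1.24 ± 0.17), and the adhesion molecule Sdk2 (1.23 ± 0.17). Among the other genes that fell were Cldn3, a tight-junction claudin (−2.63 ± 0.36), Tbc1d5 (−1.62 ± 0.20), the membrane-anchored semaphorin Sema7a (−1.26 ± 0.16) and the chromatin organiser Satb1 (−1.25 ± 0.17). Plcxd2 (−1.15 ± 0.15), Grm2, a presynaptic metabotropic glutamate receptor (−1.07 ± 0.14), and Gucy1a1, a subunit of soluble guanylate cyclase (−1.05 ± 0.14), complete the 18. Plcxd2 and Gucy1a1 lie outside the rule for named genes and were named after their values were seen, as were the examples from lists below that the methods name. At an unadjusted p under 0.05 there were 1732 genes, where chance alone gives 1141. The calls lie near the threshold. With Emx1Cre mutant 2 left out 1 gene was called (0 of the 18), with NexCre mutant 1 left out 1 (1 of the 18) and with NexCre mutant 2 left out 0 (1502 at an unadjusted p under 0.05). Leaving out Emx1Cre control 1 gave 7 (6 of the 18), Emx1Cre control 2 gave 8 (3 of the 18), Emx1Cre mutant 1 gave 28 (8 of the 18) and either NexCre control 27 (16 of the 18). DESeq2 called 300 genes, including all 18. With the replicate number of the Emx1Cre line as a batch term, which follows its split in small RNA, 73 genes were called, including all 18. Each line fitted alone gave 0 calls in Emx1Cre mutants (1181 at an unadjusted p under 0.05), and a covariate from Y-linked genes, chosen after seeing the data, left 3 of the 18.

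**Figure D2:**
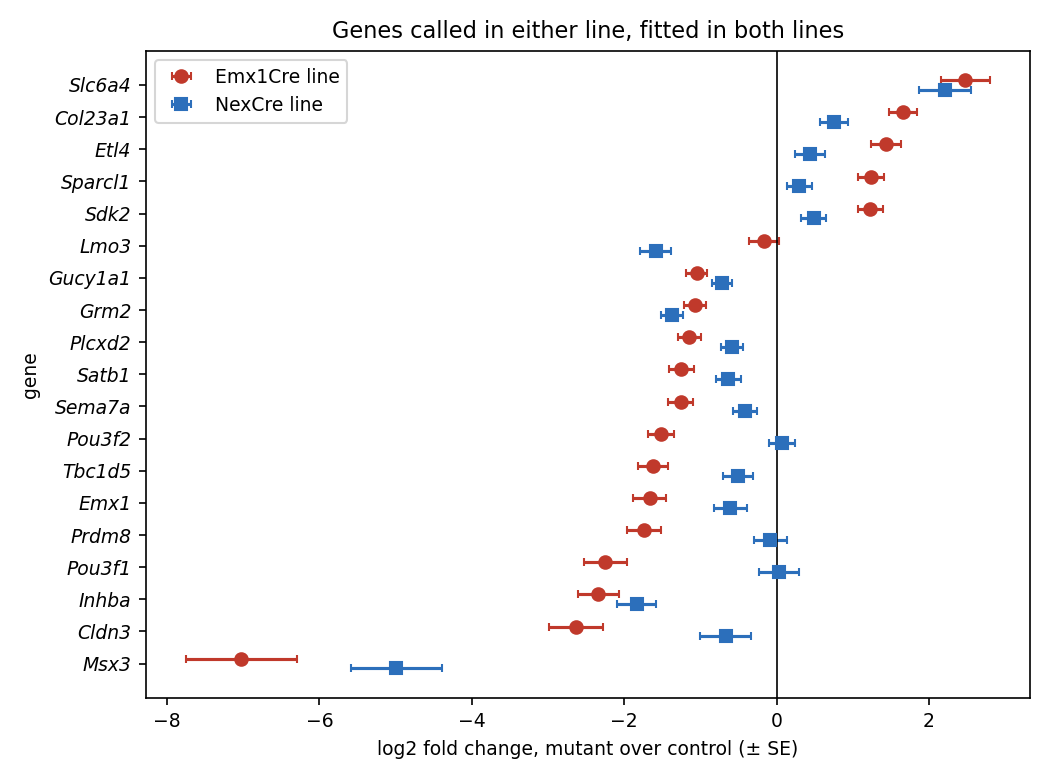
Log2 fold change (horizontal axis) with its standard error for the 19 genes called in either line that are not pseudogenes or unnamed gene models, with Emx1Cre and NexCre mutants each against their own controls. Slc6a4 is at 2.48 and 2.21, Inhba at −2.34 and −1.83, and Pou3f1 at −2.24 and 0.03 in the Emx1Cre and the NexCre line.

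Markers of cortical layers were examined as groups fixed before the data were examined. Of 15 upper-layer markers, 3 fell over all genes (Inhba, Pou3f2 and Pou3f1) and 12 were not called. Adjusted over the list alone, 8 were lower and 1 higher, the lower ones including Mef2c at −1.16 ± 0.24 and Rorb, a marker of layer 4 neurons, at −1.27 ± 0.34. The list's median log2 fold change was −0.59, and camera with a preset correlation gave an adjusted p of 6.99e-15, against an adjusted p of 0.297 with an estimated correlation. Leaving out single libraries gave medians of −0.86 (without Emx1Cre control 1) to −0.38 (without Emx1Cre control 2). None of the 20 subplate neuron markers was called by edgeR over all genes, with 1 higher and 4 lower at an unadjusted p under 0.05, and DESeq2 called 3 lower. Adjusted over the list alone, 4 were lower: Cplx3, a complexin of subplate neurons (−1.81 ± 0.27), Kcnab1 (−1.08 ± 0.18), Nxph4 (−1.23 ± 0.27) and Ccn2 (−0.54 ± 0.17). Cplx3 stood at 51.2 and 62.7 CPM in controls and at 19.4 and 13.1 CPM in mutants, and Nr4a2, another subplate marker, at 93.8 and 98.0 and at 146 and 137 CPM. The median of the subplate list was 0.03, its mean −0.16 and the direction of its test down (adjusted p = 0.0165, and adjusted p = 0.297 with an estimated correlation). The subplate call was lost without NexCre control 2 (adjusted p = 0.167) and with the batch term in both lines (adjusted p = 0.107). The 17 deep-layer markers had 0 called members by edgeR (0 higher and 4 lower at an unadjusted p under 0.05, 1 lower by DESeq2) and a median of −0.09 with an adjusted camera p of 0.0532. The 9 Cajal-Retzius markers fell as a set, with 0 members called by edgeR or DESeq2, 2 lower at an unadjusted p under 0.05, a median of −0.43 and an adjusted p of 0.0106 (adjusted p = 0.462 with an estimated correlation). Their median was 0.18 without Emx1Cre control 2, and their adjusted p was 0.121 without Emx1Cre mutant 2.

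Markers of astrocytes rose as a set in Emx1Cre mutants. All 14 lay above their control level, 11 were higher when adjusted over the list alone, and 1, Sparcl1, was called over all genes. Examples are Agt, angiotensinogen (3.46 ± 0.53), Aqp4, the water channel of astrocyte endfeet (1.51 ± 0.34), Apoe (1.15 ± 0.25), Aldh1l1 (1.06 ± 0.21) and the glutamate transporter Slc1a2 (0.89 ± 0.22). The list's median was 0.91, with an adjusted camera p of 3.88e-27 and an adjusted p of 0.181 with an estimated correlation, and leaving out single libraries gave medians of 0.82 to 1.04. Endothelial and pericyte markers also rose as a set, with a median of 0.51 and all 17 members above their control level (adjusted p = 2.23e-09, and adjusted p = 0.297 with an estimated correlation). Their median was 0.33 without Emx1Cre mutant 1. The radial glia list passed as a set with a median of 0.21 (adjusted p = 0.000696, and adjusted p = 0.501 with an estimated correlation). Slc1a3 (0.75 ± 0.19) and Lrig1 (1.12 ± 0.29), which were not called over all genes, had its lowest p-values, and the median was 0.06 and the adjusted p 0.828 without Emx1Cre control 2. The oligodendrocyte list passed as a set with a median of 0.19 (adjusted p = 0.0165, and adjusted p = 0.481 with an estimated correlation), a call lost without Emx1Cre mutant 2 (adjusted p = 0.294). None of these last 3 lists had a member called by edgeR over all genes. At an unadjusted p under 0.05 there were 7 higher for endothelium, 3 for radial glia and 0 for oligodendrocytes, and DESeq2 called 0, 2 and 0.

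Several of the sets that rose did so with the library that stood apart, Emx1Cre mutant 2. Meningeal and fibroblast markers had a median of 2.27 with 10 of 13 higher when adjusted over the list alone (adjusted camera p = 2.74e-17, and adjusted p = 0.297 with an estimated correlation). Without Emx1Cre mutant 2 their median was 1.11. Col1a1, a fibrillar collagen, stood at 1.81 and 4.24 CPM in controls, 10.5 CPM in mutant 1 and 40.7 CPM in mutant 2. Interneuron markers had a median of 0.62 (adjusted p = 1.52e-07, and adjusted p = 0.462 with an estimated correlation), and a median of 0.18 with an adjusted p of 0.237 without that library. Sst, a peptide of interneurons, stood at 119.9 CPM in mutant 1 and 292 CPM in mutant 2. Microglial markers had a median of 0.48 (adjusted p = 0.000247, and adjusted p = 0.501 with an estimated correlation), and 0.0033 without mutant 2 (adjusted p = 0.621). The striatal list had a median of 1.07 (adjusted p = 0.00433, and adjusted p = 0.554 with an estimated correlation) and a median of −0.37 without mutant 2 (adjusted p = 0.123). With the replicate number as a batch term in both lines its call was also lost (median 0.69, adjusted p = 0.0985). The thalamic list, with Slc6a4 called, had a median of 0.53 (adjusted p = 0.0031, and adjusted p = 0.501 with an estimated correlation), and 0.17 without mutant 2 (adjusted p = 0.237). Hippocampal markers, with Wfs1 at 1.09 ± 0.25 and Prox1 at 1.02 ± 0.24, had a median of 0.24 with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00286, and adjusted p = 0.446 with an estimated correlation). Their median was 0.59 without mutant 1, and no lower than 0.24 whichever library was left out, while the call was lost without mutant 2 (adjusted p = 0.0958) and without Emx1Cre control 1. Of these 6 lists edgeR called Slc6a4 alone over all genes. At an unadjusted p under 0.05 there were 11 higher for meninges, 9 for interneurons, 3 for microglia, 3 for striatum, 2 for thalamus and 5 (with 1 lower) for hippocampus, and DESeq2 called 6, 0, 0, 0, 1 and 3 higher.

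**Figure D3:**
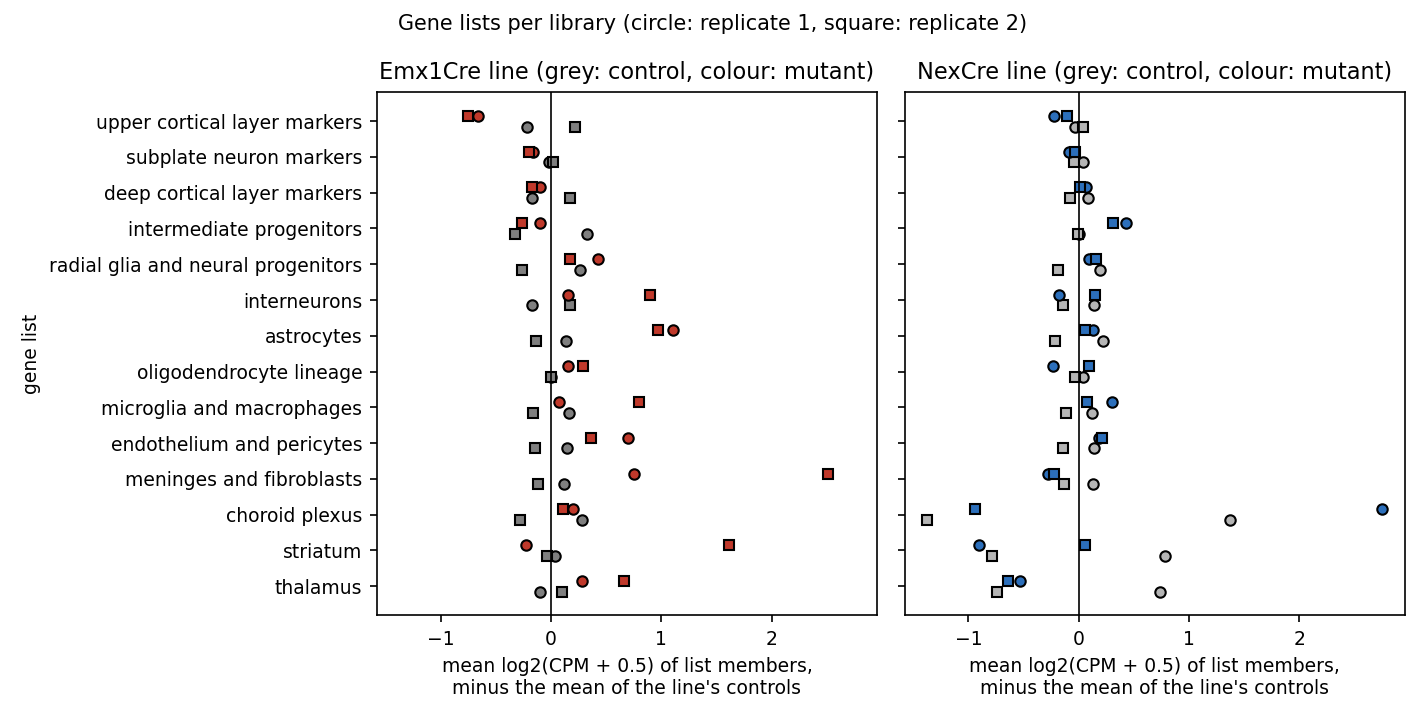
Mean log2(CPM + 0.5) of the members of 14 gene lists (vertical axis) in each library (points), as the difference from the mean of that line's 2 controls (horizontal axis, log2 units), with 1 panel per line. Astrocyte markers lie at 1.11 and 0.97 in Emx1Cre mutants 1 and 2 and striatal markers at −0.23 and 1.61.

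Few genes of the wiring and signalling lists were called over all genes. Of 65 guidance cues and receptors, Sema7a alone was called over all genes, and 3 were lower and 1 higher when adjusted over the list alone. These were Sema7a, the ephrin Efna5 (−1.60 ± 0.31) and its receptor Epha4 (−0.85 ± 0.17), and, on the higher side, the plexin Plxnc1 (1.43 ± 0.32), a receptor of Sema7a. The guidance list did not pass as a set (median −0.08, adjusted p = 0.524). Receptors of glutamate and GABA rose as a set while Grm2 fell. Their median was 0.22, with 4 higher and 1 lower adjusted over the list alone, among them Gria1 (0.66 ± 0.17) and Gabrb1 (0.75 ± 0.20). That call (adjusted p = 7.99e-05, and adjusted p = 0.481 with an estimated correlation) was lost without Emx1Cre control 1 (adjusted p = 0.413). The extracellular matrix list rose with a median of 0.22 (adjusted p = 0.000696, and adjusted p = 0.297 with an estimated correlation) and 1 called member, Sparcl1. Neither the area patterning list (median −0.05, adjusted p = 0.350) nor the adhesion list (median −0.07, adjusted p = 0.279) passed, although Dmrt3, at 3.79 ± 0.71, and Cdh4, at 1.27 ± 0.24, were called when adjusted over the list alone, which gave 2 higher and 3 lower for area patterning and 3 higher and 4 lower for adhesion. It also gave 1 higher and 1 lower each for ion channels, synaptic vesicle genes and immediate early genes, 1 higher and 2 lower each for intermediate progenitors and piriform markers, 0 higher and 2 lower for neurotrophic factors, and 1 higher for interneurons. The remaining lists that did not pass as sets had 0 members called by edgeR. They were ion channels (median 0.02, adjusted p = 0.700, with 6 higher and 4 lower at an unadjusted p under 0.05, and 1 higher and 1 lower by DESeq2), synaptic vesicle genes (0.05, adjusted p = 0.472, 3 and 4, DESeq2 1 and 1) and immediate early genes (0.14, adjusted p = 0.679, 4 and 3, DESeq2 1 and 1). In the same order of values, intermediate progenitors had −0.12 (adjusted p = 0.129, 1 and 2, DESeq2 1 and 1), with Insm1 at −1.71 ± 0.29, and neurotrophic factors 0.13 (adjusted p = 0.287, 2 and 3, DESeq2 0 and 2), with Ngfr at −1.52 ± 0.26 and Hgf at −1.74 ± 0.31. Piriform and amygdala markers had 0.04 (adjusted p = 0.507, 2 and 3, DESeq2 0 and 1). DESeq2 called 0 members in the other 6, which were cell cycle (median −0.000117, adjusted p = 0.464, 1 and 1), choroid plexus (−0.0051, adjusted p = 0.524, 0 and 0), erythroid cells (0.42, adjusted p = 0.116, 0 and 0), ribosomal proteins (0.06, adjusted p = 0.164, 1 and 0), stress response (−0.11, adjusted p = 0.159, 0 and 1) and apoptosis (−0.04, adjusted p = 0.427, 0 and 1).

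The comparison of NexCre mutants with their controls asks what changes when Lhx2 is removed from postmitotic excitatory neurons. The limit given above for the Cre allele holds here too, and Lhx2 itself was not lower in these mutants. Msx3 fell in the libraries labelled NexCre mutant by 4.99 ± 0.60 on the log2 scale, from 315 and 349 reads to 8 and 15. Lmo3, a LIM-only transcriptional cofactor (chromosome 6, 138362918 to 138581968), fell by 1.58 ± 0.20, from 212 and 188 to 68.8 and 64.6 CPM. Grm2 (chromosome 9, 106643095 to 106656082) fell by 1.38 ± 0.15, from 63.8 and 66.9 to 24.3 and 26.0 CPM. The adjusted p-values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.0378, 0.0462 and 0.0212.

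Altogether 7 genes were called in NexCre mutants, 4 higher and 3 lower, with 904 at an unadjusted p under 0.05, where chance alone gives 1141. The 4 higher ones are pseudogenes or gene models without a name, which the rule for named genes leaves out, and they are given here because their values were seen. Hist1h2al, a histone pseudogene (chromosome 13, 51202727 to 51203065), stood at 18 and 11 reads in controls and at 1471 and 2740 reads in mutants. Ccl19-ps3, a chemokine pseudogene (chromosome 4, 42132559 to 42134171), had 0 reads in both controls and 103 and 171 reads in mutants, which makes it at least 83.2-fold higher against a floor of 3 reads over the group, for counting error alone. Gm2564, on the same chromosome (42629719 to 42631714), had 2 and 0 reads in controls and 72 and 53 in mutants. Gm3279, a lincRNA on chromosome 6 (55684571 to 55694574), had 5 and 9 reads in controls and 175 and 270 in mutants, and it lies next to Neurod6. In Emx1Cre control 1, control 2, mutant 1 and mutant 2, Ccl19-ps3 had 695, 406, 493 and 720 reads and Gm2564 had 238, 158, 331 and 278. For both genes the NexCre controls thus had the lowest counts of all groups, and the cause was not tested. Histone genes and the stretch of chromosome 4 that holds Ccl19-ps3 and Gm2564 have near-identical copies, so reads could be split between copies and the values of Hist1h2al, Ccl19-ps3 and Gm2564 are uncertain. With protein-coding genes alone in the test, edgeR called 0 genes in NexCre mutants, with 641 at an unadjusted p under 0.05. Leaving out NexCre control 1 gave 1 call, mutant 1 gave 2, mutant 2 gave 3, either Emx1Cre mutant gave 13 and NexCre control 2 gave 43. DESeq2 called 78 genes, including all 7.

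The thalamic and synaptic lists moved in NexCre mutants. Receptors of glutamate and GABA fell as a set (median −0.17, adjusted p = 0.00401 by camera), with Grm2 called over all genes and 2 of 37 lower adjusted over the list alone. Synaptic vesicle genes fell as a set (median −0.12, adjusted p = 0.00754), with 0 called by edgeR or DESeq2 and 4 lower at an unadjusted p under 0.05, led by Sv2c at −0.80 ± 0.28. The intermediate progenitor list passed upward as a set (median 0.45, adjusted p = 0.00961), with 0 members called by edgeR or DESeq2, 1 higher at an unadjusted p under 0.05, and Sstr2 at 0.57 ± 0.18 and Mfng at 0.52 ± 0.26. Thalamic markers fell as a set (median −0.48, adjusted p = 0.030), with Lhx9 at −5.14 ± 1.35 while Slc6a4 had 2.21 ± 0.34 and an adjusted p of 0.101 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Erythroid markers (median −0.38, adjusted p = 0.0316) and ribosomal proteins (median −0.06, adjusted p = 0.030) also fell as sets, with 0 members called by edgeR or DESeq2 and 0 and 2 lower at an unadjusted p under 0.05. The thalamic list had 0 called by edgeR over all genes, 1 higher and 6 lower at an unadjusted p under 0.05, and 1 higher and 1 lower by DESeq2. All 6 had an adjusted p of 0.779 with an estimated correlation. Each of these calls was lost without a single library. Without NexCre control 1, which stood apart for thalamic markers, the thalamic median was 0.14 (adjusted p = 0.392), and the receptor and erythroid lists had adjusted p-values of 0.211 and 0.715. Without NexCre mutant 1 the vesicle and progenitor lists had 0.360 and 0.166. The vesicle median there was −0.00679, while the progenitor median stayed between 0.37 and 0.45 whichever library was left out. Without NexCre mutant 2 the ribosomal median was 0.0049 with an adjusted p of 0.858. With the replicate number as a batch term in both lines the thalamic call was lost (adjusted p = 0.0587).

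No other list passed as a set in NexCre mutants, and edgeR called no member of these over all genes except Lmo3. The subplate list had a median of −0.09 (adjusted p = 0.357), 0 members called by edgeR or DESeq2 and 3 higher and 3 lower at an unadjusted p under 0.05. Cplx3 stood at 0.903, 1.42, 0.973 and 0.679 CPM across the 4 NexCre libraries, a low level at which a change is hard to see. Of the 20 subplate markers, 13 were lower and 3 higher in NexCre controls than in Emx1Cre controls, with a median of −1.55. The results of this list in the 2 lines are therefore not directly comparable. The upper-layer list had a median of −0.06 (adjusted p = 0.120) and 1 member lower adjusted over the list alone, Inhba at −1.83 ± 0.26, while Pou3f2 was at 0.07 ± 0.17 and Pou3f1 at 0.03 ± 0.26. Astrocyte markers had a median of 0.18 (adjusted p = 0.160). Choroid plexus markers had a median of 1.98 (adjusted p = 0.0502), with Ttr high in mutant 1. Meningeal markers differed in sign, with a median of 0.11, a mean of −0.32 and a test direction of down (adjusted p = 0.224). Area patterning genes had a median of 0.20 (adjusted p = 0.762) with Lmo3 called, and piriform markers −0.20 (adjusted p = 0.0893) with the same gene. Deep-layer markers had 0.00833 (adjusted p = 0.358), guidance genes 0.06 (0.362), adhesion molecules −0.05 (0.112), matrix genes 0.06 (0.762), ion channels −0.10 (0.0502), immediate early genes 0.14 (0.745) and radial glia markers 0.12 (0.194). Cell cycle genes had 0.12 (0.151), interneurons −0.01 (0.615), oligodendrocytes −0.09 (0.399), microglia 0.36 (0.0787), endothelium 0.20 (0.0502), Cajal-Retzius cells −0.30 (0.0583), striatum −0.71 (0.0583) and hippocampus 0.00906 (0.745). The stress list had −0.06 (0.358), the apoptosis list −0.09 (0.371) and the neurotrophic list −0.14 (0.239). Adjusted over the list alone, Npy (interneurons, −0.73 ± 0.16) and Ptn (radial glia, −0.72 ± 0.16) were lower and Bcl2l11 (apoptosis, 0.90 ± 0.24) higher, the area patterning list had 1 higher and 2 lower, and the thalamic list had 1 higher and 2 lower.

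Genes that moved in both lines were compared next, with different control libraries in each line. Msx3 and Grm2 fell in both, where 0.00171 shared genes are expected of independent lists (Fisher's exact p = 8.98e-07 for genes lower). The lists are not independent, since each gene's spread was estimated once from all 8 libraries. A gene with a low estimate can pass in both lines, so that p and the expected numbers here overstate the agreement. At an adjusted p under 0.10 Inhba joined them. At an unadjusted p under 0.05, 65 genes were lower in both lines against 15.9 expected, 49 were higher in both against 17.4 expected, and 49 went opposite ways against 35.3 expected. Of the 18 genes called in Emx1Cre mutants, 16 had the same sign in NexCre mutants, 12 of them at an unadjusted p under 0.05. Across all 22820 genes, which are not independent replicates, the log2 fold changes of the 2 lines had a Pearson correlation of 0.0158. Without Emx1Cre mutant 2, NexCre control 1, NexCre mutant 1 or NexCre mutant 2, 0 genes were called in both lines, and without Emx1Cre control 1, Emx1Cre control 2 or NexCre control 2, 1 was. Leaving out Emx1Cre mutant 1 gave 3.

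The difference between the 2 mutant effects was tested directly. Hist1h2al differed, with an Emx1Cre effect minus NexCre effect of −7.19 ± 0.59 and an adjusted p of 0.00618 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was the only gene called of 22820, with 1242 at an unadjusted p under 0.05, and DESeq2 called 100. Genes with the largest differences among the lowest p-values were not called, and each had an adjusted p of 0.384 or 0.433 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. On the lower side these were Pou3f1 (−2.28 ± 0.38), Prdm8 (−1.66 ± 0.31), Pou3f2 (−1.59 ± 0.24), Igfbpl1 (−1.40 ± 0.21) and Ier5 (−1.38 ± 0.24). On the higher side they were Plac9a (3.78 ± 0.64), Snhg11 (2.87 ± 0.51), S100a10 (1.48 ± 0.25), the selenium carrier Selenop (1.43 ± 0.27) and Gsg1l (1.32 ± 0.22). As sets, astrocyte markers differed by a median of 0.83 (adjusted p = 3.36e-13) and upper-layer markers by −0.51 (adjusted p = 1.56e-07), and both had an adjusted p of 0.516 with an estimated correlation. In all, 16 of 31 lists passed the camera test of the difference, 13 up and 3 down, and 0 with an estimated correlation, and edgeR called no member of any list over all genes. Leaving out NexCre control 2 gave 31 called genes, Emx1Cre control 2 gave 8, Emx1Cre mutant 1 gave 7, Emx1Cre mutant 2 gave 3 and Emx1Cre control 1 gave 2, and leaving out Emx1Cre mutant 2 gave 8 lists.

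Controls of the 2 lines, both labelled wild type, were compared to show how far the 2 sets of libraries differ with no deletion. Subplate markers were lower in NexCre controls, with 13 of 20 lower, 3 higher and a median of −1.55. Cplx3 was lower by −5.60 ± 0.33, Ccn2 by −2.83 ± 0.18 and Nr4a2 by −2.71 ± 0.36 on the log2 scale. Upper-layer markers were higher, with 10 of 15 higher, 1 lower and a median of 1.32, among them Rorb (2.73 ± 0.35), Unc5d (2.51 ± 0.16) and Pou3f2 (2.31 ± 0.18). Oligodendrocyte markers were lower in 12 of 13 cases, with a median of −1.60, Gpr17 at −4.03 ± 0.33 and Mbp at −1.92 ± 0.17.

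In that comparison 10456 of 22820 genes were called, 6059 higher and 4397 lower in NexCre controls, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The genes with the largest differences were histone and small nuclear RNA genes on the higher side, whose copies are near-identical: Hist1h3f, Scarna6, Hist1h3e, Rnu2-10 and Hist1h3b. Hist1h3f had 0 CPM in both Emx1Cre controls and 131 and 135 CPM in NexCre controls. On the lower side they were the brain cytoplasmic RNA Bc1 (−5.71 ± 0.58), Cplx3, Lor (−4.96 ± 0.46), Prrt1 (−4.41 ± 0.51) and Enpp6 (−4.25 ± 0.68). With protein-coding genes alone 6214 were called. Of 31 lists, 11 passed the camera test and 0 with an estimated correlation. The lists that passed, each with its adjusted p and then its adjusted p with an estimated correlation, were subplate (3.48e-07, 0.119), oligodendrocyte (7.06e-08, 0.365) and upper layer (0.000175, 0.678). Synaptic vesicle genes were lower with a median of −0.92 (7.06e-08, 0.678), among them Vamp2 at −3.08 ± 0.21. Members called higher and lower were 5 and 21 for synaptic vesicles, 0 and 9 for astrocytes, 4 and 30 for ribosomal proteins, 2 and 10 for stress, 30 and 7 for guidance, 0 and 8 for microglia, 12 and 0 for cell cycle and 0 and 7 for endothelium. Astrocyte markers had −1.10 (0.000202, 0.678), ribosomal proteins −0.32 (0.000306, 0.832), stress genes −0.71 (0.0184, 0.365), guidance genes 0.52 (0.0308, 0.804), microglia −0.74 (0.0308, 0.832), cell cycle genes 0.70 (0.0333, 0.832) and endothelium −0.74 (0.0333, 0.832). The calls of guidance, microglial and endothelial markers were lost without Emx1Cre control 1 (adjusted p = 0.0692, 0.0721 and 0.0933), the microglial call also with the replicate number as a batch term (adjusted p = 0.0975), and cell cycle genes without Emx1Cre control 2 had a median of 0.25 (adjusted p = 0.234). The line, the composition of the libraries and any difference in tissue are the same split of the samples here and cannot be told apart.

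**Figure D4:**
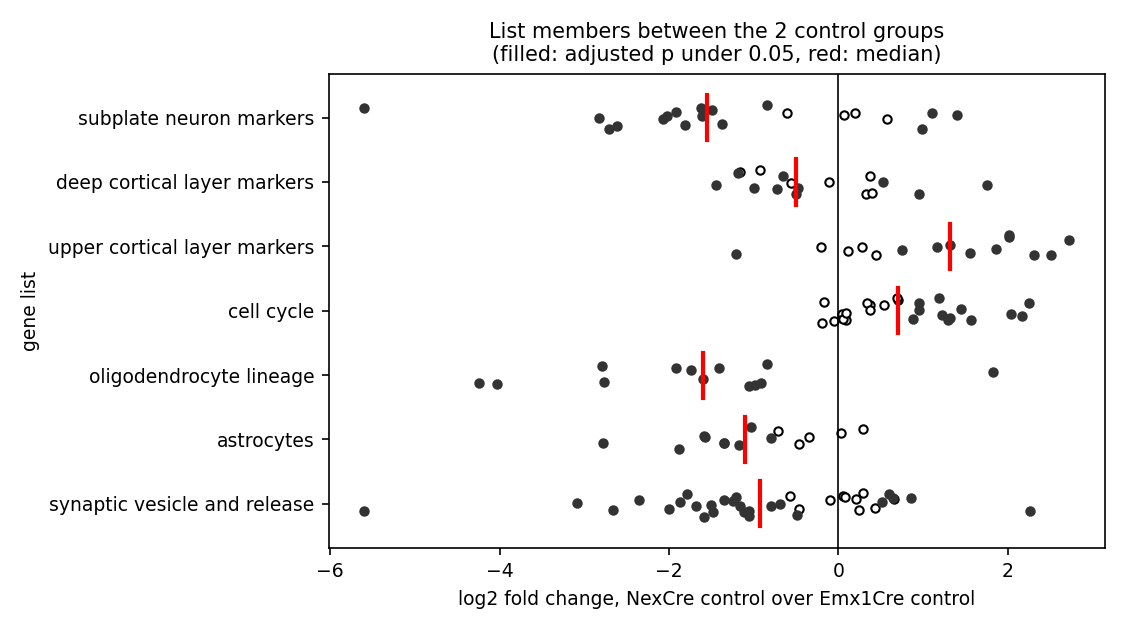
Log2 fold change of NexCre controls over Emx1Cre controls (horizontal axis) for each tested member of 7 gene lists (vertical axis), with filled points for genes called at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and a red line at each list's median. The median of subplate markers is −1.55 and that of upper-layer markers 1.32.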

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

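All tests of explanations in this part were chosen after the results were seen. Results are listed here because the effect in Emx1Cre mutants differed from the effect in NexCre mutants by a test of the difference itself. The only gene was Hist1h2al, at −7.19 on the log2 scale, a histone pseudogene with near-identical copies, so its value is uncertain. Among lists, by the camera test with a preset correlation, the median difference was −0.32 for deep layers, −0.51 for upper layers, −0.38 for intermediate progenitors, 0.19 for extracellular matrix, 0.33 for glutamate and GABA receptors, 0.19 for synaptic vesicles, 0.49 for interneurons and 0.28 for oligodendrocytes. It was 0.83 for astrocytes, 0.31 for endothelium, 2.30 for meninges, 0.76 for erythroid cells, 1.80 for striatum, 0.69 for thalamus, 0.41 for hippocampus and 0.15 for ribosomal proteins. With an estimated correlation 0 of these lists passed. Only upper layers, glutamate and GABA receptors, astrocytes and meninges kept their call whichever library was left out. Without Emx1Cre mutant 2 the median was 0.25 for striatum (adjusted p = 0.990) and 0.96 for meninges, without Emx1Cre control 2 it was −0.11 for deep layers (adjusted p = 0.689), and without Emx1Cre control 1 it was 0.0111 for synaptic vesicles (adjusted p = 0.927).

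Markers of subplate neurons were lower in NexCre controls than in Emx1Cre controls. With only protein-coding genes outside the histone families in scaling and test the median was −1.50 (bootstrap SE 0.414, 20 genes). Protein-coding genes, histones included, already held 90.4% to 93.0% of reads in the controls, so this step could move the scaling only slightly. It therefore does not weigh RNA selection, whose effect on single genes was not tested. After a spline on transcript length and GC, which took up 10.1% of the variance, it was −1.41 (SE 0.294), which speaks against a bias of that kind. Upper-layer markers had a median of 1.32 (SE 0.455), so tissue of another depth, region or stage remains a candidate explanation. The line and the set of libraries are the same split, so this stays open.

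Markers of astrocytes and other non-neuronal cells were higher in Emx1Cre mutants. A lower share of neurons that raised every other cell type alike was tested with the difference between the astrocyte and oligodendrocyte medians. It was 0.72 (two-sided permutation of 27 members, p = 9e-05). That p takes genes as independent, which co-regulated genes are not, and leaves out differences between pools. Whichever library was left out, the astrocyte median was at least 0.82 and the oligodendrocyte median at most 0.37, which speaks against an equal rise of these 2 lists. Without Emx1Cre mutant 2 the astrocyte median was 0.99 (bootstrap SE over genes 0.131). Striatal and meningeal tissue in that pool alone therefore does not account for the astrocyte markers. The mean of meningeal markers also lay above the controls in mutant 1, by 0.75 against 2.51 in mutant 2, so meningeal tissue in both pools is not excluded. Of the striatal markers 13 of 16 were more than 2 times higher in mutant 2 than in mutant 1, which restates the pattern that prompted the test and leaves its source open.

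Lhx2 was not lower in NexCre mutants. Exchanged labels were tested with the genes lower in Emx1Cre mutants at an unadjusted p under 0.05: 65 were lower and 16 higher in the libraries labelled NexCre mutant (exact binomial p = 3.64e-08, with genes taken as independent, which co-regulated genes are not). Over both directions 65 genes were lower and 49 higher in both lines against 49 that went opposite ways, which speaks against an exchange, less clearly for the genes that were higher. Reads from exons outside the deleted part remain open, since the log2 fold change of 0.18 covers the whole gene. Lhx2 from cells without NexCre activity also remains open: 17 of 17 radial glia markers had a mean of at least 1 CPM in NexCre mutants, and values per cell type were not analysed here.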

How the results depend on the processing

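The tests with protein-coding genes only, the Y-linked covariate and the replicate block in the Emx1Cre line only were chosen after seeing the data. The counts of genes called kept within 1.5 times their value under RLE and upper-quartile scaling and the strict filter. They also did so with mitochondrial, haemoglobin and sex-linked genes removed. Over all settings together, 4711 values of named genes kept their direction and side of the threshold, 195 became stronger, 164 weaker and 4 reversed. Values called in neither fit count as kept, and values from the comparison of the controls are included. The 4711 therefore do not measure how stable the calls in mutants are. Of list values, by the direction of the list test, 353 kept their direction and side of the threshold, 124 became weaker and 3 reversed. Pairs of numbers below are genes higher and lower. With no low-count filter there were 373 and 212 in Emx1Cre mutants, 89 and 162 in NexCre mutants, 408 for the difference of effects and 29 in both lines. DESeq2 gave 175 and 125, 34 and 44, 100, and 14. Each line fitted alone gave 0 and 0 in Emx1Cre mutants (1181 at an unadjusted p under 0.05), 6 and 11 in NexCre mutants and 0 in both lines. Protein-coding genes only gave 0 and 0 in NexCre mutants, 0 for the difference, 6214 for the controls and 0 in both lines. The Y-linked covariate gave 0 and 3 in Emx1Cre mutants, 1 and 0 in NexCre mutants and 0 in both lines. With an estimated correlation 0 lists passed in Emx1Cre mutants, 0 in NexCre mutants and 0 for the difference. The cause was not tested.

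The labels give controls and mutants the same replicate numbers, which may or may not mark paired samples. In the Emx1Cre line libraries with the same number also had a like share of small RNA, as given above. The replicate block gave 39 and 43 in Emx1Cre mutants, 12 and 10 in NexCre mutants, 5 for the difference of effects and 5 in both lines. In the Emx1Cre line only, the replicate block gave 27 and 46, 9 and 12, 3, and 5. Deviations from the group mean of libraries with the same number had a correlation of 0.193 in the Emx1Cre line and 0.0917 in the NexCre line, and of 0.321 and 0.168 over genes with a mean of at least 1 CPM. The cause was not tested.

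Leaving out single libraries leaves 1 library in a group, which is assumed to vary like the others. Genes called ranged from 0 to 15 higher and 0 to 14 lower in Emx1Cre mutants, 1 to 5 and 0 to 38 in NexCre mutants, 1 to 31 for the difference, 7074 to 10949 for the controls and 0 to 3 in both lines. Lists called ranged from 8 to 19 in Emx1Cre mutants, 3 to 13 in NexCre mutants and 8 to 18 for the difference. Values that reversed ran, in Emx1Cre mutants, from −0.63 (without mutant 1) to 0.00583 (without mutant 2) for Neurod6 and from −0.34 (without mutant 2) to 3.45 (without mutant 1) for Six3. The striatal median ran from −0.37 (without mutant 2) to 1.75 (without mutant 1). In NexCre mutants Ebf3 ran from −4.68 (without control 2) to 0.22 (without control 1), Sostdc1 from −0.0233 (without mutant 1) to 3.42 (without control 1), and the thalamic median from −0.91 (without control 2) to 0.14 (without control 1). The median of ribosomal proteins for the difference ran from −0.0402 (without Emx1Cre mutant 2) to 0.30 (without Emx1Cre mutant 1). Other medians changed sign while the direction of the list test did not: in Emx1Cre mutants subplate markers from 0.03 to −0.15 (without mutant 1) and Cajal-Retzius markers from −0.43 to 0.18 (without control 2), and in NexCre mutants ribosomal proteins from −0.06 to 0.00486 (without mutant 2). The cause was not tested. Replicates differed by more than counting error in every group (chi-square per degree of freedom of 25.9 to 87.7), so depth was not the only limit.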

Other observations

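The test of the hypothesis in this part was chosen after the results were seen. The hypothesis was that Lhx2 loss acts on the same genes in both lines, tested as the mean of the 2 mutant effects against their difference divided by 2, which has the same error. The mean gave 35 called genes and the difference 1 in edgeR's quasi-likelihood test, while 1581 and 1242 genes had an unadjusted p under 0.05. Effects that add more often than they oppose would give such counts, although the pools could also share other causes. Without NexCre control 2 more genes were called for the difference than for the mean, so the comparison rests in part on that library. Of the 35, 13 were higher and 22 lower. The call does not make each of them shared: Hist1h2al (−0.19 in Emx1Cre and 7.00 in NexCre mutants), Ccl19-ps3 (0.29 and 10.23), Gm2564 (0.68 and 5.68) and Gm10601 (0.77 and 9.32) were carried by the NexCre line, and Hist1h2al is also the gene called for the difference. Both NexCre controls had 0 CPM for Ccl19-ps3 and Gm10601, so the NexCre values of these genes depend on the prior count and are not exact. Sparcl1 (1.24 and 0.30), Cldn3 (−2.63 and −0.67) and Etl4 (1.44 and 0.44) were carried by the Emx1Cre line. Leaving out single libraries gave 7 (without NexCre control 2) to 63 (without Emx1Cre mutant 1).

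The genes called for the mean by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, named after their values were seen, include Msx3 (−6.01 ± 0.47), Grm2 (−1.22 ± 0.10), Inhba (−2.09 ± 0.19, adjusted p = 0.00319), Slc6a4 (2.35 ± 0.23, adjusted p = 0.00721), Dmrt2 (2.73 ± 0.32, adjusted p = 0.0178), the activin antagonist Fst (−2.18 ± 0.28, adjusted p = 0.0244) and the ephrin Efna5 (−1.46 ± 0.22, adjusted p = 0.0413). Ostn had 45 and 27 reads in Emx1Cre controls and 23 and 30 in NexCre controls, and 0 in all 4 mutants, which is at least 22.9-fold and 19.4-fold lower for counting error alone.

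Among genes within 1 Mb of Ccl19-ps3 on chromosome 4, 66 were tested. In NexCre mutants 16 were higher and 2 lower at an unadjusted p under 0.05, and in Emx1Cre mutants 3 and 0. Over all 22820 genes, 386 were higher and 518 lower in NexCre mutants. The same window there gave 1 higher and 6 lower of 52 around Grm2 and 0 and 3 of 32 around Msx3. Around Neurod6 it gave 1 and 0 of 16, and around Gm3279 0 and 1 of 15. The windows of Lhx2 (40 tested), Emx1 (32), Hist1h2al (11) and Lmo3 (6) had 0 and 0. The cause was not tested.

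Sex-linked transcripts differed between pools. Xist had 4905, 827, 876 and 2471 reads in Emx1Cre control 1, control 2, mutant 1 and mutant 2, and 2127, 82, 22667 and 262 in the NexCre libraries in the same order. Ddx3y, on the Y chromosome, had 144, 1004, 1540 and 0 reads, and 1799, 2334, 0 and 2586. The Y-linked genes Eif2s3y, Kdm5d and Uty had 0, 0 and 0 reads in Emx1Cre mutant 2 and 2, 2 and 4 in NexCre mutant 1. Every control pool had Y-linked reads. Sex was thus unbalanced between controls and mutants in both lines, and its effect was not told apart from that of genotype. The covariate from Y-linked genes left 3 of the 18 calls in Emx1Cre mutants.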
